A study of Mus musculus with 16 samples.

How the data were processed

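The study profiled E2f4, H3K4me2 and H3K27ac by ChIP-seq in mouse liver 40 h after partial hepatectomy, at postnatal day 90 and on a mixed C57/B6 and 129 background, per the labels. Tissue had been frozen and was fixed in 1% formaldehyde for 20 min, and hepatocytes were then isolated, per the labels' protocols. Of the 16 samples, 8 were immunoprecipitations with a peak list each and 8 were inputs whose data were not used here. Groups and replicate numbers were taken from the sample titles, with 2 libraries per genotype for E2f4 and 1 per genotype for each mark.

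Bowtie2 2.2.3, Picard, MACS2 2.0.10.20131216 and HOMER, with build mm10, are named in the submitters' processing notes, which give no role for any of them. The lists are in the narrowPeak form for E2f4 and the broadPeak form for the marks, 1 list per library, so that peaks were called per library and not on pooled replicates. How the inputs entered the calling is not given in the sources used here. Each deposited list gives the position of a peak and the fold enrichment over background, a ratio that belongs to that peak alone. The deposited lists also give −log10 p-values and −log10 q-values, the lowest −log10 q-value being 1.33 in the E2f4 lists and 1.00 in the histone lists. The deposited score is 10 times the −log10 q-value as a whole number and was not used, and the deposited summit offset placed E2f4 summits. Fold and −log10 q-value were used only to rank or filter peaks within a list, since they move with depth and enrichment. The lists hold no counts, so depth is unknown, and a library with less depth or weaker enrichment yields fewer peaks at the same threshold.

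Gene positions came from an NCBI RefSeq table of assembly GRCm38.p6, which has the coordinates of build mm10, with 21887 protein-coding genes on chromosomes 1 to 19, X and Y. The table holds the outer ends of each gene and no strand, exons or transcripts. The design had assumed annotated transcription start sites. In their place the marked gene end was used, the end with more H3K4me2 within 2000 bp summed over both genotypes, with H3K27ac deciding ties, and both ends where neither decided (6018 genes). Promoters inside genes are missed by this choice, and whether a site was exonic or intronic was not analysed here. A gene carried E2f4 when a summit lay within 1000 bp of the marked end, so that summits of a gene in several libraries need not belong to overlapping peaks. Neighbours that share a promoter both count. No genome sequence was used, so the planned search for the E2F motif was not run.

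E2f4 libraries were compared by peak number with an exact permutation test, and by overlap of at least 1 bp. Regions of both WT libraries are merged peaks supported by both. Shares have exact Clopper-Pearson 95% intervals over regions. Before the data were examined, 16 gene lists with 420 entries were written (419 matched the table), covering cell cycle, repair, chromatin, SWI/SNF, regeneration, liver and other cell types, together with the tests, the alternatives and the rule for named genes. List membership was tested against a summit in both WT libraries by Fisher's exact test over 15074 genes with H3K4me2 at the marked end, and, among genes with a summit in both WT libraries, against a summit in a KO library, with Benjamini-Hochberg adjustment over lists. For the marks, the length covered within 5000 bp of the marked end was compared per gene, and a list's mean difference was placed among 10000 random lists of the same size matched on quintile of mean covered length. This percentile describes the 2 libraries and is not a p-value. A further 7 lists (B cells, T and NK cells, endothelium, macrophages, neutrophils, and male-biased and female-biased liver genes) were written after the first lists had been seen. They share no gene with the first 16 except Prom1.

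Named genes followed a fixed rule. For E2f4 it took up to 10 genes with a summit in both WT and no KO library, up to 8 with one in all 4, up to 6 with one in both KO libraries only, up to 4 members per list and up to 3 distal regions, by mean rank of −log10 q-value. For each mark it took up to 6 genes marked in WT only and 6 in KO only by the authors' fold, and up to 3 list members in each direction, and Arid1a, E2f4, Alb, Hnf4a, Ccnd1, Cdkn1a and Cebpa always. Other list members with values, the 11 genes named among the 19 without a KO summit, the genes of the 7 later lists, of the histone clusters and of symbol families with their neighbours, and Xist were chosen after their values were seen.

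Alternatives were stricter −log10 q-values (5 and 10), other windows (500, 5000 and 10000 bp), other overlap rules (50% of the shorter peak, summits within 200 bp, regions under 1000 bp apart merged), lists of equal length, another background, autosomes and X alone, and each E2f4 library left out. The functions were tested on simulated data. A planted list of 50 genes at 60% against 5% was called in 100% of 20 runs over 21887 genes, with 0% of 300 unchanged lists called. A shift of 500 bp in 30 of 3000 genes with an SD of 900 bp was found in 90% of 10 runs and one of 250 bp in 30%, and 6% and 1% of the unchanged lists lay outside the central 95%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.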

Results

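The series measured where the transcription factor E2f4 and the histone marks H3K4me2 and H3K27ac lay in the genome of regenerating mouse liver, by chromatin immunoprecipitation and sequencing (ChIP-seq). Livers were collected 40 h after partial hepatectomy, the surgical removal of most of the organ, after which the remaining hepatocytes re-enter the cell cycle. E2f4 is a member of the E2F family that binds cell cycle genes together with the RB-related pocket proteins, H3K4me2 marks promoters and enhancers, and H3K27ac marks those that are active. The compared genotypes were Arid1a WT (both alleles floxed, no Cre) and Arid1a KO (the same alleles with Cre under the albumin promoter, which acts in hepatocytes). Arid1a is a DNA-binding subunit of the SWI/SNF chromatin remodelling complex. E2f4 had 2 libraries per genotype, and each histone mark had 1 library per genotype, so that no histone difference below has a replicate check. The labels do not say that replicates came from separate animals, so the spread between them may be technical. The question set by the design was how the occupancy of E2f4 and the extent of both marks differed between the genotypes.

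Each of the 8 libraries was represented by the authors' list of called peaks, without read counts, so the sequencing depth is unknown. The E2f4 lists held 1791 and 1058 peaks in WT and 287 and 683 in KO, with median widths of 207, 212, 185 and 213 bp. The H3K4me2 lists held 66832 regions in WT and 73042 in KO, and the H3K27ac lists held 63321 and 54652. A gene was counted as carrying a summit or a mark when it lay within 1000 bp of the gene's marked end, the annotated end with more H3K4me2. A peak missing from a list was not called there, which does not show that the protein was absent. Intervals below cover counting error only.

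The targeted gene itself could not check the labels, since the lists hold no read coverage and the labels do not say which part of Arid1a was deleted. At the marked end of Arid1a (chromosome 4, 133679008 to 133756769, build mm10) all 2001 bp of the window of 1000 bp either side were covered by both marks in both genotypes. No E2f4 summit was called there in any of the 4 libraries.

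In WT liver E2f4 summits were over-represented at the promoters of mitotic, DNA replication and DNA repair genes, and the strongest E2f4 sites were called in KO liver too. Most genes with a summit in both WT libraries, 666 of 803, were in none of the 16 gene lists, and 130 were in the lists of cell cycle, replication, repair and chromatin genes. Among the 803 genes were Bub1 and Ttk (spindle checkpoint kinases), Kif20a (a mitotic kinesin), Rrm2 (a ribonucleotide reductase subunit), Brca1 (a homologous recombination factor) and E2f3 (an activating E2F). KO libraries held fewer peaks, 485 ± 280 (SD, n = 2) against 1424.5 ± 518 (SD, n = 2) in WT, or 34.0% of the WT mean. The exact permutation test over the 6 assignments of 4 libraries, two-sided, gave p = 0.333, the smallest it can give, so that the difference could not pass a threshold of 0.05. Genes with a summit numbered 1377 and 986 in WT and 238 and 680 in KO, or 459 ± 313 (SD, n = 2) against 1181.5 ± 276 (SD, n = 2), again with an exact permutation p of 0.333.

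Most E2f4 sites called in KO liver were also called in WT liver. Of 792 regions with a peak in both WT libraries, 556 (70.2%, exact binomial 95% interval 66.9 to 73.4) overlapped a peak of either KO library. KO replicate 1 held 27.8% of them and KO replicate 2 held 69.7%, a mean of 48.7% ± 29.6 (SD, n = 2). With each list limited to its 287 strongest peaks this mean was 81.8%. In the other direction, all 217 regions with a peak in both KO libraries overlapped a peak of WT replicate 1, and 215 overlapped one of WT replicate 2. Over all peaks the overlap was lower, with 78.7% and 77.0% of the KO replicate 1 peaks and 86.8% and 85.8% of the KO replicate 2 peaks overlapping WT replicates 1 and 2. Of the 803 genes, 228 had a summit in both KO libraries, 350 in 1 of them and 225 (28.0%) in neither. The 231 genes shared with KO replicate 1 and the 575 shared with KO replicate 2 compared with 12.7 and 36.2 genes expected from independent lists of those sizes. No gene had a summit in both KO libraries and in no WT library, and 31 genes had one in 1 KO library and in no WT library. With the 803 genes ordered by WT peak strength, the share with a KO summit was 99.5% in the strongest 201, 90.5% in the next 201, 68.0% in the next 200 and 29.9% in the weakest 201. These shares rest on KO replicate 2, and without it they were 81.1, 25.4, 7.5 and 0.995%. Without KO replicate 2 the mean number of KO peaks was 20.1% of WT and the number of genes 20.1%, and the share of regions was 27.8%; without WT replicate 2 the mean share over the KO libraries was 22.8%.

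**Figure D1:**
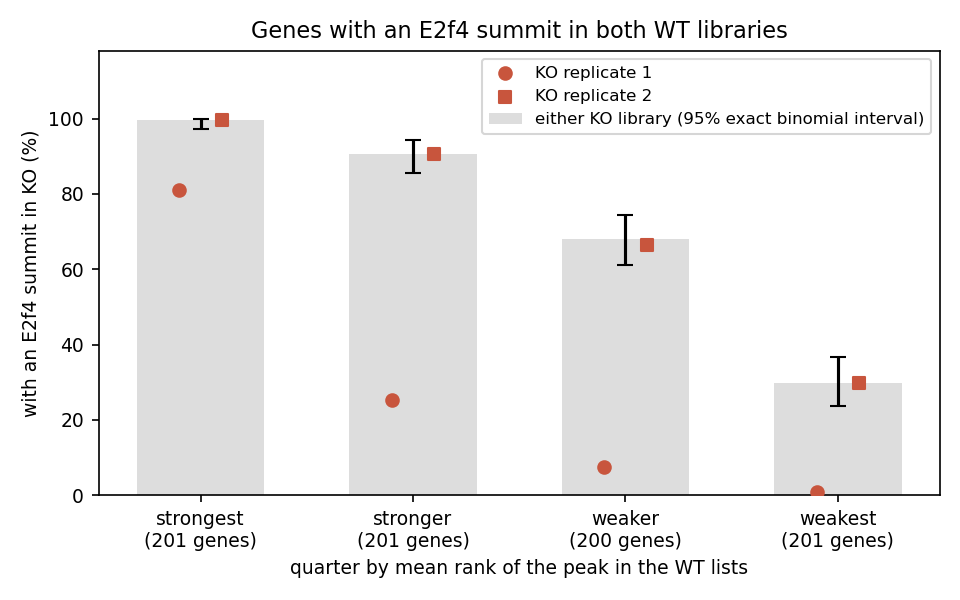
Share of the genes with an E2f4 summit in both WT libraries that also had one in KO liver (vertical axis, percent), in 4 classes of the mean rank of the WT peak (horizontal axis, 200 or 201 genes each). Bars show either KO library with the exact binomial 95% interval and points show each KO library, and the bars go from 99.5% in the strongest class to 29.9% in the weakest, and the points of KO replicate 1 from 81.1% to 0.995%.

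The 5 lists of cell cycle, replication, repair and chromatin genes were over-represented among these genes, and mitotic genes led. Of the 57 G2/M and mitosis genes with H3K4me2 at the marked end, 49 (86.0%) had a summit in both WT libraries, against 5.02% of the other 15017 genes (odds ratio 116, Fisher's exact test with Benjamini-Hochberg adjustment over 16 lists, adjusted p = 1.70e-53). By the same exact test the share was 33 of 52 for G1/S and DNA replication (63.5%, odds ratio 32.1, adjusted p = 1.16e-28). It was 21 of 30 for DNA repair and checkpoint (70.0%, odds ratio 42.6, exact test, adjusted p = 6.78e-20) and 18 of 29 for chromatin, condensin and cohesin (62.1%, odds ratio 29.7, adjusted p = 7.89e-16). Of the E2F, RB and DREAM components, 9 of 18 carried a summit (50%, odds ratio 18.0, exact test, adjusted p = 3.33e-07), among them E2f3, E2f8, Lin9 and the pocket protein gene Rbl1. At Rbl1 the strongest peaks of WT replicates 1 and 2 did not overlap. Negative regulators of the cell cycle had 4 of 22 (Ccng2, Wee1, Cdkn2a and Cdkn2c), which did not pass the exact test (odds ratio 3.96, adjusted p = 0.0724). The SWI/SNF subunits had 2 of 18 (Brd9 and Smarcd2, exact test, adjusted p = 0.480) and the regeneration signalling and immediate early genes 1 of 27 (Myc, adjusted p = 1). None of the 161 genes of the 8 liver and cell type lists, which cover hepatocyte identity and secreted proteins, hepatic metabolism, fetal and progenitor liver, cholangiocytes, macrophages, endothelium, stellate cells and fibroblasts, and lymphocytes, had a summit in any of the 4 libraries. Depletion was not detected by the exact test in any of these lists (lowest adjusted p = 0.480), since only 5.34% of other genes had a summit in both WT libraries. Alb, Hnf4a, Cebpa, Ccnd1 and E2f4 also had none at their marked ends, and promoters inside these genes were not examined. The annotated end used for Cdkn1a had none either. It carried neither mark within 1000 bp and therefore says nothing of the promoter of that gene. These tests run across genes, which are not replicates, and describe these libraries.

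**Figure D2:**
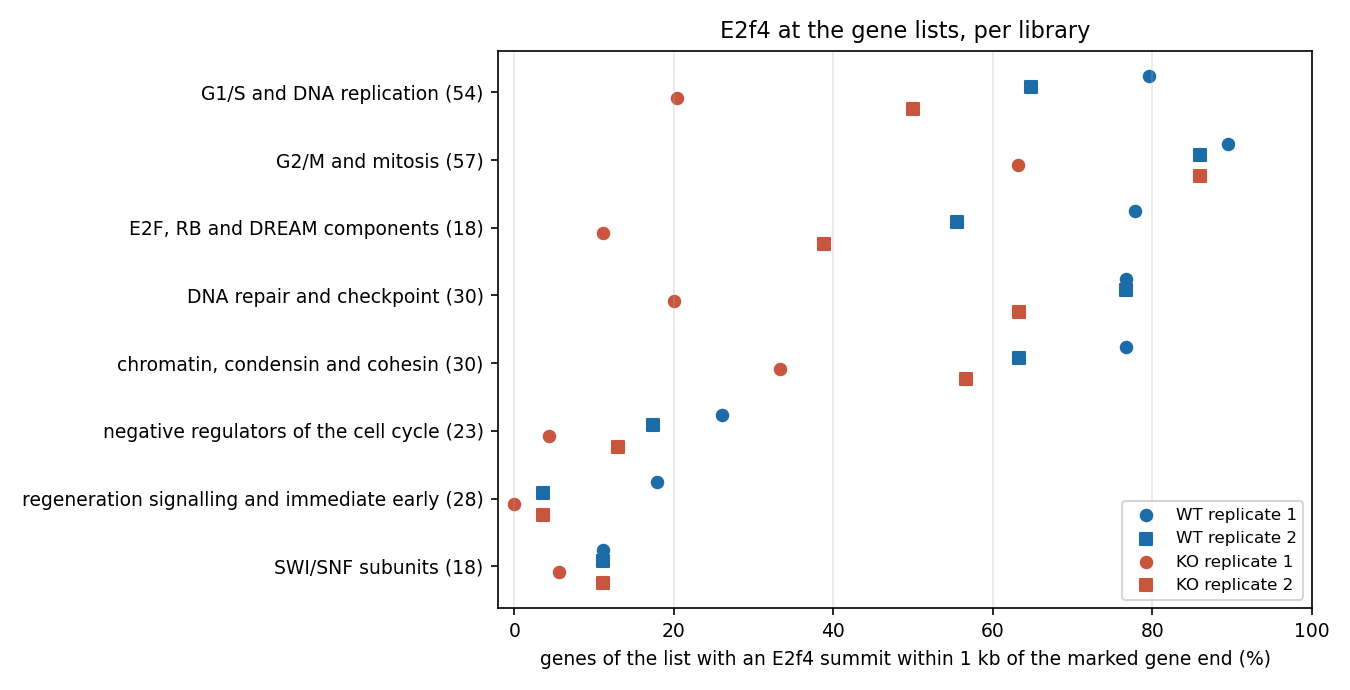
Share of the genes of each list with an E2f4 summit within 1 kb of the marked gene end (horizontal axis, percent) in the 4 libraries, for the 8 lists with a summit in both WT libraries (vertical axis, list size in brackets). The G2/M and mitosis list stood at 89.5% and 86.0% in WT and at 63.2% and 86.0% in KO, and the G1/S list at 79.6% and 64.8% in WT and 20.4% and 50% in KO.

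Mitotic genes held their E2f4 summits in KO liver more often than all other genes together, but an excess over genes with equally strong WT peaks was not detected in the KO libraries together. Of the 49 G2/M genes with a summit in both WT libraries, 47 (95.9%) had one in a KO library, against 70.4% of the other genes (odds ratio 9.87, Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 0.000178). Their WT peaks were also stronger, with a median rank of 110.5 against 423 for the other genes. Random lists matched on WT rank held a mean of 92.6% (95% of them between 87.8 and 98.0%), and the G2/M list lay at percentile 86.9 among them. These random lists could themselves draw G2/M genes, and retention of the strongest peaks was near its ceiling, so an excess was hard to detect. No difference from the remaining genes was detected by the same exact test for the other lists, with 25 of 33 G1/S genes (75.8%, adjusted p = 1), 18 of 21 DNA repair genes (85.7%, adjusted p = 0.873), 15 of 18 chromatin genes (83.3%, adjusted p = 1) and 6 of 9 E2F, RB and DREAM genes (66.7%, adjusted p = 1). The odds ratio for the G2/M list was 15.5 without WT replicate 1 and 32.0 without WT replicate 2, and in the second case the DNA repair list (odds ratio 4.45) and the chromatin list (3.49) passed the test too. Without KO replicate 2 the share was 73.5% for G2/M genes against 25.9% of the other genes (odds ratio 7.94), 33.3% for G1/S, 28.6% for DNA repair, 50% for chromatin and 22.2% for E2F, RB and DREAM genes. Over these 5 lists, 130 genes had a summit in both WT libraries and 19 of them had none in KO. The 19 included the replication genes Fen1, Mcm6, Pole, Pola2 and Chaf1b, the mitotic genes Bub1b and Cenpa, the MuvB component genes Lin54 and Rbbp4, the checkpoint kinase gene Atr and the Polycomb methyltransferase gene Ezh2.

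Single genes illustrate both classes, with ranks taken by −log10 q-value within a list and the authors' fold enrichment given only to describe a peak. E2f3 (chromosome 13, 29906575 to 29986064) had the peaks ranked 5 and 5 in the WT lists and 4 and 2 in the KO lists. The summit shared by Kif20a and Brd8 on chromosome 18 (peak from 34624656 to 34625086 in WT replicate 1) ranked 9 and 3 in WT and 2 and 3 in KO, and the 2 genes, which overlap there, cannot be told apart. The other genes with the highest ranks over all 4 libraries were the histone gene H3c8 on chromosome 13, Bub1 on chromosome 2, Depdc1a on chromosome 3, and Cdca5 (a cohesin regulator) with its neighbour Zfpl1 on chromosome 19. The promoters of Brca1 with Nbr1, Cdca3 with Usp5, Brd9 with Trip13 and Smarcd2 with Tcam1 are likewise shared. Further strong members called in all 4 libraries were Rrm2, Cdc7 and Gins3 (replication), Ttk and Cdca3 (mitosis), Neil3, Mms22l and Brip1 (repair), and Hmgb2, Ncapg2, Ncaph and Hmgb1 (chromatin). Uhrf1, a reader of hemimethylated DNA, ranked 32 and 71 in the WT lists and was called in KO replicate 2 only, at rank 94. Among genes with a summit in both WT libraries and no KO library the strongest was Shmt2, a mitochondrial enzyme of one-carbon metabolism (chromosome 10, peak from 127521844 to 127522179 in WT replicate 1, fold 20.9, rank 161, and rank 192 in WT replicate 2). Pdk4, an inhibitor kinase of pyruvate dehydrogenase, followed on chromosome 6 with ranks 148 and 288. The next were Mkks and Slx4ip (shared promoter), Gle1, Fen1 with Tmem258 (shared promoter), Terf2 (a telomere binding protein), Ndc1 and Setd5, with mean WT ranks from 284 to 313. At Mkks and Slx4ip the ranked peaks of WT replicate 1 (136892019 to 136892267) and WT replicate 2 (136890760 to 136890982) did not overlap. They are therefore separate sites.

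**Figure D3:**
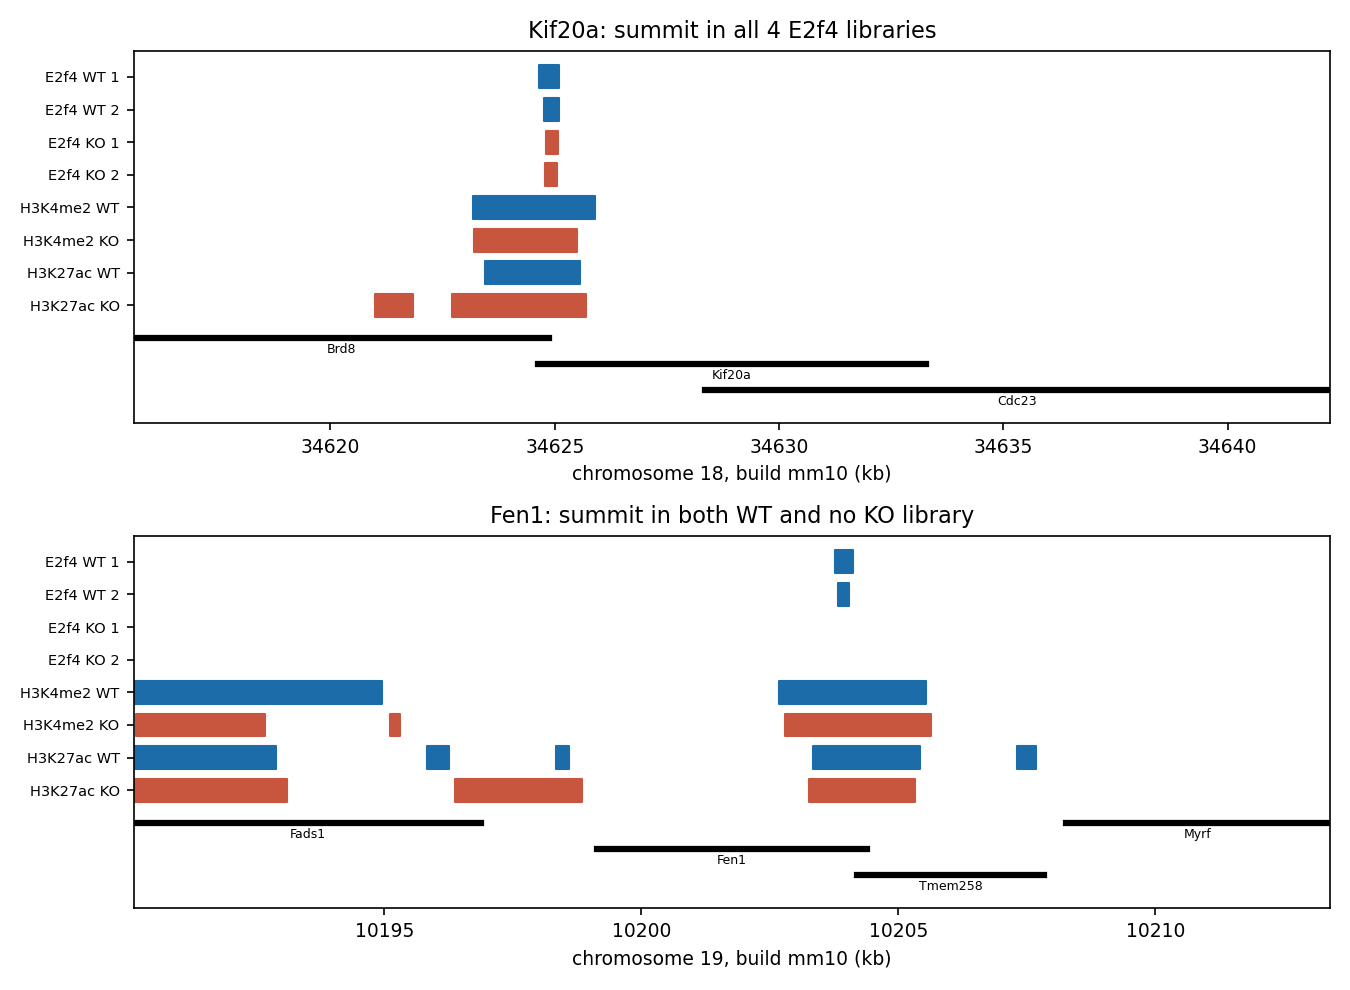
Called peaks at Kif20a (chromosome 18) and Fen1 (chromosome 19) in the 8 libraries, drawn to scale in kb of build mm10, with WT in blue, KO in red and annotated protein-coding genes as black lines. The E2f4 peak at Kif20a is called in all 4 libraries, the one at Fen1 in both WT libraries only, and both marks cover both sites in both genotypes.

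Few of the E2f4 sites shared by both WT libraries lay far from genes, and more of the sites called in single libraries did. Of the 792 regions of both WT libraries, 20 lay more than 10000 bp from any annotated gene end, non-coding genes included. Of these 20, 10 overlapped a KO peak. Over all peaks, 242 of 1791 and 71 of 1058 in WT and 46 of 287 and 31 of 683 in KO lay that far away. The strongest of the 20 shared regions lay on chromosome 10 (44005629 to 44005965, called in KO replicate 2), chromosome 5 (135394473 to 135394793, called in both KO libraries) and chromosome 1 (57995879 to 57996283, called in KO replicate 2). At the level of single libraries, 66.0% and 77.6% of WT peaks and 69.7% and 83.5% of KO peaks had their summit at a marked gene end.

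H3K4me2 covered less of lymphocyte genes and more of endothelial genes in the KO library than in the WT library. All 11 lymphocyte genes with any mark within 5000 bp of the gene end were covered over a shorter length in KO, by a mean of -2669 bp (from 4049 to 1380 bp), below all 10000 random lists of the same size matched on covered length. Cd2 went from 3712 bp to 0, Cd79b (a B cell receptor subunit) from 4503 bp to 0, Cd3e from 1654 bp to 0 and Ptprc, the pan-leukocyte gene, from 5095 to 1704 bp. Of the 15 endothelial genes 14 were covered over a longer length, by a mean of 1362 bp (from 3468 to 4831 bp), above all random lists. Pecam1 went from 2725 to 5877 bp, Lyve1 from 3018 to 5803 bp and Vwf from 0 to 1460 bp. These lists mark other cell types than hepatocytes, although the labels' protocol says that hepatocytes were isolated.

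Genes of hepatic metabolism and of the cell cycle also had shorter H3K4me2 regions in the KO library, beside the lymphocyte and endothelial differences given above. Hepatic metabolism genes differed by a mean of -473 bp from 6604 bp in WT (24 of 40 shorter, percentile 0.01 among random lists, median -256.5 bp). Cyp2e1 went from 10001 to 5466 bp, Cyp8b1 (a bile acid hydroxylase) from 6069 to 3483 bp and Hpd from 8548 to 6198 bp. The mean difference was -217 bp for G1/S genes (percentile 0.04), -150 bp for G2/M genes (percentile 0.19) and -229 bp for chromatin genes (percentile 0.53), whereas random lists averaged between 151 and 187 bp longer in KO. The remaining lists lay within the central 95% of random lists, with percentiles of 2.70 for DNA repair, 4.30 for E2F, RB and DREAM components, 4.68 for hepatocyte identity, 7.73 for macrophages, 35.1 for negative cell cycle regulators, 49.6 for fetal liver and for SWI/SNF subunits, 58.8 for regeneration signalling, 95.3 for stellate cells and fibroblasts and 97.3 for cholangiocytes. Of these, DNA repair left that range within 1000 bp (1.96) and at a −log10 q-value of at least 5 (1.47). With either gene end or with lists of equal length cholangiocytes left it (98.4 and 98.0), as did stellate cells and fibroblasts within 10000 bp and with either end (99.98 and 99.4), and macrophages in lists of equal length (0.57).

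Over the genome H3K4me2 covered 104 Mb in WT and 112 Mb in KO, 107% of the WT length. Of the WT regions 79.6% (exact binomial 95% interval 79.3 to 79.9) overlapped a KO region and 71.9% of KO regions overlapped a WT region, and the shared length was 62.3% of the union. Regions found in 1 library were narrower than shared ones, with a median of 440 against 1195 bp in WT and 409 against 1263 bp in KO. Marked promoters numbered 14528 in WT and 14766 in KO, of which 308 were marked in WT only and 546 in KO only. The WT-only promoters with the highest authors' fold were Plk5, Cend1, Zfp217, Sema4c, Spatc1 and Ccdc152, and the KO-only ones Ager, Ltk, Masp2, Dync2h1, Ssc4d and Reep5. Each of the 12 genes had at least 1035 bp of the mark within 5000 bp in the other genotype, so the mark was not absent from their surroundings. Among list genes, those marked within 1000 bp in WT only included Spp1, Colec11, Des, Cd2, Cd3e and Cd79b, and those in KO only Rfc1, Aif1, Clec4f, Timd4 and Vwf. Rfc1 was covered there over 26 bp only. Within 5000 bp Aif1 and Clec4f had more of the mark in WT (2669 against 2159 bp and 2321 against 1398 bp). The other list genes named here had more in the genotype with the marked promoter. Alb, Ccnd1, Cebpa and E2f4 were covered over the full 2001 bp in both genotypes. The annotated end used for Hnf4a was covered over 1367 and 1430 bp, and that used for Cdkn1a over 0 bp in both.

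**Figure D4:**
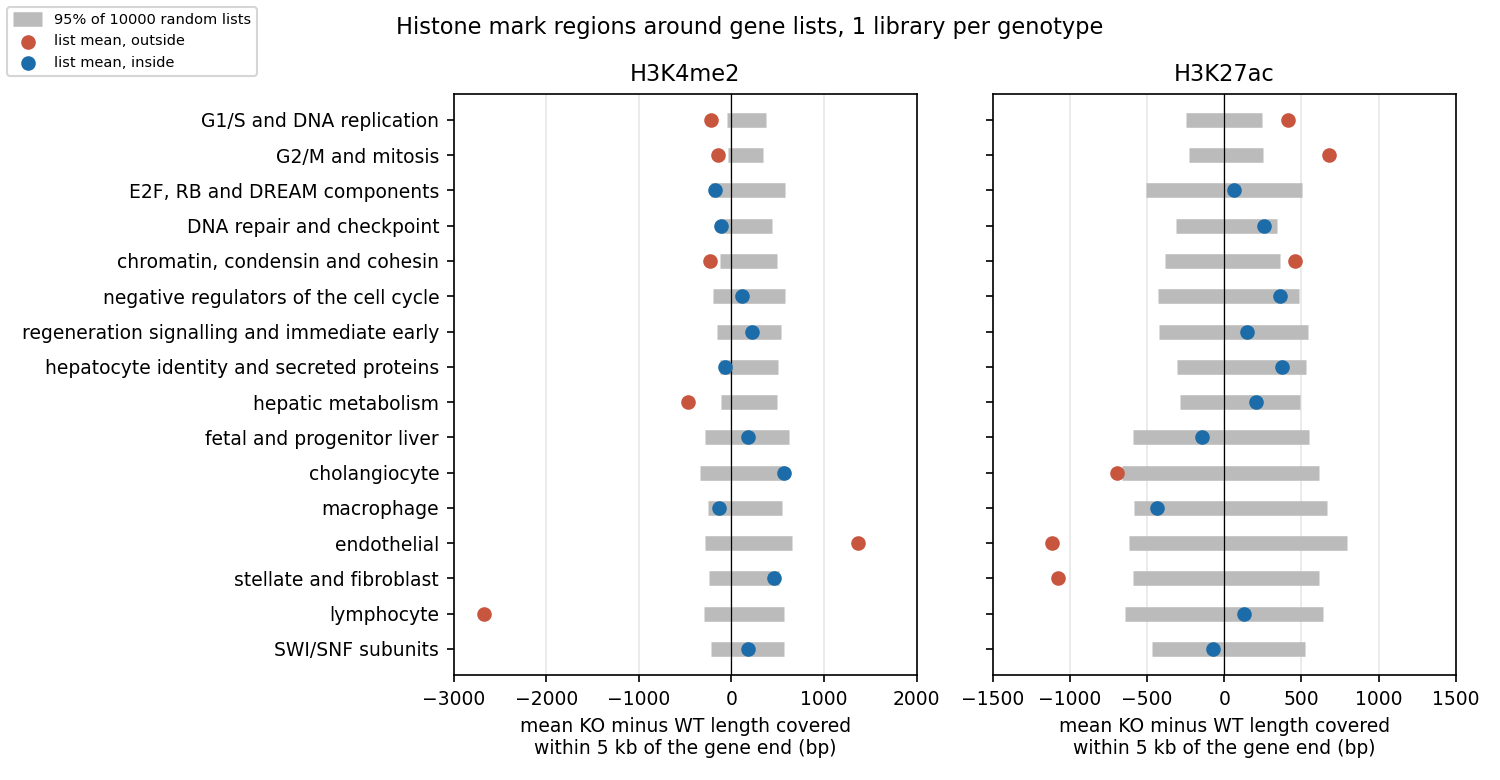
Mean difference in covered length, KO minus WT, within 5 kb of the marked gene end (horizontal axes, bp) for the 16 gene lists (vertical axis) in H3K4me2 and H3K27ac. Points are list means and grey bars hold 95% of 10000 random lists matched on covered length; red points lie outside the bars, such as lymphocyte genes at -2669 bp in H3K4me2 and G2/M genes at 678 bp in H3K27ac.

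H3K27ac covered more of cell cycle genes in the KO library than in the WT library. Of 57 G2/M genes 47 had a longer covered length in KO, by a mean of 678 bp (from 1899 to 2576 bp), above all random lists. Top2a went from 537 to 2688 bp, Plk1 from 1301 to 3032 bp, Cdk1 from 2694 to 4918 bp, and Cenpf, Cdc25c and Cenph from 0 to 1904, 1136 and 802 bp. G1/S genes were longer by 410 bp (38 of 54, percentile 99.96), with Gins3 from 0 to 711 bp and Rfc1 from 2163 to 5350 bp, and chromatin genes by 461 bp (23 of 30, percentile 99.32). Ccnd1, the cyclin D1 gene, went from 6554 to 9094 bp. Some lists of other cell types went the other way, with endothelial genes at -1114 bp (percentile 0.07), stellate and fibroblast genes at -1077 bp (percentile 0.05) and cholangiocyte genes at -695 bp (percentile 2.03). The endothelial value lay inside the random range in a window of 1000 bp (percentile 6.03). The cholangiocyte value did so in windows of 1000 and 10000 bp and at a stricter threshold (percentiles 10.3, 6.73 and 12.9 in that order).

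The 2 H3K27ac libraries also differed at sex-linked genes, and this difference lay beside every H3K27ac difference given here. The WT list held 10 regions on chromosome Y, among them regions at Kdm5d (897528 to 898416), Eif2s3y, Uty and Ddx3y, and the KO list held 2, both between 90744381 and 90761791 where the WT list also had regions. The H3K4me2 lists held 1 and 2 regions on chromosome Y, in the same part of it. Within 5000 bp of the higher-coordinate end of Xist, the RNA gene of X inactivation, H3K27ac covered 0 bp in WT and 3536 bp in KO, and H3K4me2 covered 6281 and 6320 bp. Genes known as male-biased in mouse liver, listed after the Y regions had been seen, were shorter in KO in H3K27ac at 13 of 14 genes, by a mean of -2487 bp (from 5600 to 3113 bp), below all random lists. Genes known as female-biased were longer at 12 of 16 genes, by a mean of 1767 bp (from 2183 to 3949 bp), above all random lists. Elovl3 went from 6152 to 473 bp, Cyp7b1 from 9076 to 1292 bp and Cyp2b9 from 1333 to 9322 bp.

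**Figure D5:**
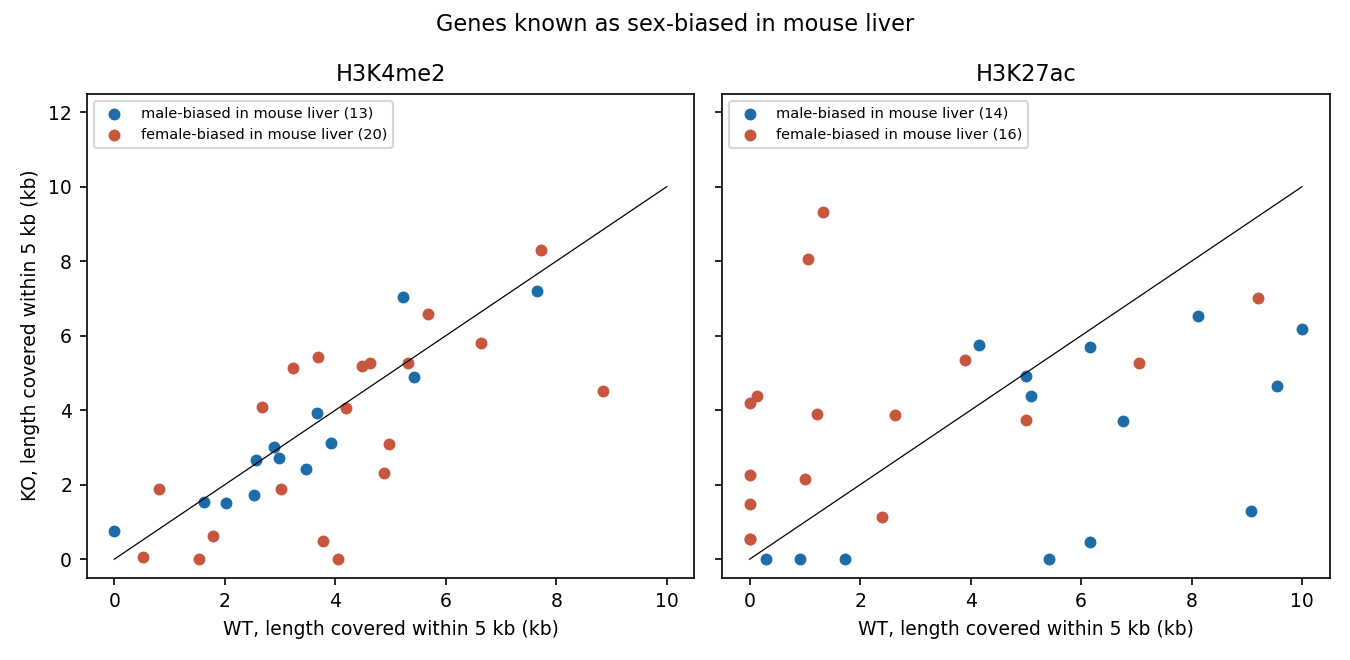
Length covered within 5 kb of the marked gene end in WT (horizontal axes, kb) and KO (vertical axis, kb) for genes known as male-biased (blue) and female-biased (red) in mouse liver, with the line of equal length. In H3K27ac 13 of 14 male-biased genes lie below the line and 12 of 16 female-biased genes above it, and in H3K4me2 the counts were 8 of 13 and 8 of 20.

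The remaining lists lay within the central 95% of random lists in H3K27ac. Their percentiles were 92.7 for DNA repair, 92.8 for negative cell cycle regulators, 88.5 for hepatocyte identity, 69.6 for hepatic metabolism, 63.6 for regeneration signalling, 58.3 for E2F, RB and DREAM components, 29.2 for fetal liver and 6.63 for macrophages. Hepatocyte identity left that range within 1000 and 10000 bp (99.0 and 99.5), and macrophages within 1000 bp and at a −log10 q-value of at least 5 (0.50 and 0). Within 1000 bp most hepatocyte identity genes were at the ceiling of 2001 bp in both genotypes. The change there lay mainly at Hnf4a (310 to 1354 bp), Serpina1a (1199 to 2001 bp) and Apob (1710 to 2001 bp), while Asgr1 was slightly shorter (1388 to 1375 bp). Lymphocyte genes (percentile 65.6) had a mean of 129 bp but a median of -149 bp, and at a −log10 q-value of at least 5 their mean was -1577 bp (percentile 2.95, still inside the random range). SWI/SNF subunits (percentile 32.4) had a mean of -75.9 bp but a median of 59.5 bp. Within 1000 bp the SWI/SNF mean was 182 bp (percentile 97.8), outside the random range in the other direction. Over the genome H3K27ac covered 113 Mb in WT and 104 Mb in KO, 92.1% of the WT length. Regions that reached within 1000 bp of any annotated gene end had a summed full length of 48.9 Mb in WT and 49.2 Mb in KO. The other regions summed to 63.7 and 54.5 Mb. Of the WT regions 65.8% (exact binomial 95% interval 65.4 to 66.1) overlapped a KO region and 75.4% of KO regions overlapped a WT region, and the shared length was 57.6% of the union. Promoters with the mark numbered 12390 and 12380, with 502 in WT only and 492 in KO only. The WT-only promoters with the highest authors' fold were Heatr4, the Y-linked Kdm5d, Cyp4a12a (a male-biased cytochrome P450), Gm10209, Dcaf12 and Csrp3. The KO-only ones were Nbeal1, H3f3b, Smco3, Igflr1, Patl2 and Ier5. Kdm5d and Cyp4a12a had 0 bp of the mark within 5000 bp in KO. Each of the other named genes had at least 1318 bp there in the other genotype, so the mark was not absent from their surroundings. In the library that had it, the mark covered from 14 bp (Heatr4) to 1528 bp (Csrp3) within 1000 bp of their ends. List genes with the mark within 1000 bp in WT only included Sox9 and Bicc1 (cholangiocyte), Col1a1 and Tcf21 (stellate and fibroblast), Cd24a, Aif1 and Cd3g. Those with it in KO only included Neil3, Cyp2c29, Prom1, Pkhd1, Klrb1c and Nkg7. Within 5000 bp Aif1 and Tcf21 had more of the mark in KO (2172 against 2349 bp and 2702 against 2982 bp, WT first). The other list genes named here had more in the genotype with the marked promoter. Alb, Cebpa and E2f4 were covered over 2001 bp in both genotypes. The annotated end used for Hnf4a was covered over 310 and 1354 bp, which leaves out any promoter inside that gene.

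Genes bound by E2f4 carried both marks whether or not the E2f4 summit was called in KO liver. H3K4me2 was present at all 578 genes with a summit in a KO library and at all 225 without one, in both genotypes. The marked end had been chosen by its H3K4me2, which favours this result, and a share at its ceiling cannot separate these classes. H3K27ac was present in KO at 99.5% of the former and 97.8% of the latter (Fisher's exact test, p = 0.0431, or 0.172 after Benjamini-Hochberg adjustment over 4 tests), and in WT at 95.5% and 96.4% (Fisher's exact test, p = 0.697). The KO difference did not pass the exact test within 500 bp (p = 0.126), at a −log10 q-value of at least 5 (p = 0.579) or without KO replicate 2 (p = 0.450). It passed the adjusted exact test only without WT replicate 2 (adjusted p = 0.0393). Genes with H3K4me2 and no E2f4 summit in any library carried H3K27ac at 79.2% in both genotypes. The covered length of H3K27ac differed between KO and WT by a mean of 424 bp at the 578 genes and 215 bp at the 225 genes, and by -1.62 bp at genes without a summit. That of H3K4me2 differed by -81.3, 14.0 and 186 bp, with 1 library per genotype and mark.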

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

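The test of G2/M retention in KO replicate 1 alone was chosen after that library's share and the first matched result had been seen, and its repeat with 40 classes of strength was unplanned. The other tests here were set after the patterns they address, but before their own results were seen. The WT H3K27ac library held 10 regions on chromosome Y, a signal outside the planned comparisons. The E2f4 lists held 16 and 6 peaks on the mitochondrial genome in WT replicates 1 and 2, likewise outside them, and 1 in each KO library, with no authors' fold above 1.57.

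KO libraries had 34.0% as many E2f4 peaks as WT libraries. The strength of the WT peak separated genes with and without a KO summit with an area under the curve of 0.878 (95% bootstrap interval 0.853 to 0.901), as it would if the KO libraries found only the strongest of the same sites. The same nesting held between the KO libraries, where the strength in replicate 2 separated genes with and without a replicate 1 summit at 0.878 (0.849 to 0.905), and there genotype plays no part. With every list shortened to its 287 strongest peaks, WT and KO lists overlapped by 71.1% on average and lists of the same genotype by 70.7%, a difference of 0.348 percentage points. These means cover unlike KO libraries. The WT lists overlapped each other by 78.4%, KO replicate 2 by 79.4 and 81.2%, and KO replicate 1 by 60.6 and 63.1%. The KO lists overlapped each other by 63.1%. These values argue against a loss of E2f4 from a distinct set of strong sites in KO replicate 2, and are less clear for KO replicate 1. Both lower sensitivity of the KO libraries and an even reduction of E2f4 occupancy may produce them, which peak lists without counts leave open. The higher retention of G2/M genes may follow from their stronger WT peaks, since it lay at percentile 86.9 of random lists matched on WT rank, but in KO replicate 1 alone its 73.5% equalled the upper bound of the matched range (percentile 97.1, and 96.5 with 40 classes), so that an excess beyond peak strength stays open.

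H3K4me2 covered less of lymphocyte genes and more of endothelial genes in the KO library. Second lists of B cell and of T and NK cell genes had no gene in common with the first lists and were also shorter in KO, by -869 bp (12 of 15 genes shorter) and -717 bp (10 of 15), each at percentile 0 of random lists. Cd22 went from 2251 bp to 0 and Il7r from 761 bp to 0, but Prf1 went from 1264 to 3059 bp, Ccl5 from 839 to 1882 bp and Cd247 from 1349 to 2182 bp, so that fewer lymphocytes in the KO material may explain part of it and not these genes. A second endothelial list was longer by 533 bp (percentile 95.1), inside the range of random lists, so that a different share of endothelial cells cannot be told apart from chance in these genes with 1 library per genotype. A lower share of hepatocytes in one library would move all other cell types alike, and lymphocyte and endothelial genes moved in opposite directions. In H3K27ac the endothelial genes were shorter in KO (-1114 bp, percentile 0.07) and the lymphocyte genes lay inside the random range (percentile 65.6). Neither H3K4me2 difference was thus seen in the H3K27ac libraries, which also differed at sex-linked genes. The labels' protocol names an isolation of hepatocytes, which would reduce both cell types, and an effect of Arid1a loss on the cells of the liver stays open as untested.

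The Y-linked H3K27ac regions of the WT library may come from animals of different sex behind the 2 H3K27ac libraries, male-biased genes then being shorter and female-biased genes longer in KO. Male-biased liver genes lay at percentile 0 and female-biased liver genes at percentile 100 of random lists in H3K27ac, and H3K27ac at Xist was called in KO only. A mislabelled or exchanged library was not tested, and a changed response of sex-biased genes to Arid1a loss would not by itself remove regions at Kdm5d, Uty and Ddx3y. In H3K4me2 both libraries covered Xist and neither had regions at those Y genes, although female-biased genes were shorter in KO there (-625 bp, percentile 0), opposite to H3K27ac. The WT lists of H3K4me2 and H3K27ac thus also differed from each other at Xist and those Y genes, which limits comparisons between the marks. Genotype and sex cannot be separated for any H3K27ac difference here, the longer regions at G2/M genes included.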

How the results depend on the processing

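Most alternative values counted as unchanged, 59 of 72 for the results that answer a comparison and 263 of 285 for single lists. Unchanged meant the same side of a threshold, a count or length within a fixed ratio, or a move within the SD or counting interval. The SD over 2 libraries was wide, 29.6 percentage points for the share of E2f4 regions, so smaller moves of that share counted as unchanged. No result past its threshold turned direction, but 16 values for lists that were not past it did, 6 odds ratios and 10 covered lengths. The odds ratio of a retained summit went from 0.776 to 2.03 for E2F, RB and DREAM genes at a −log10 q-value of at least 5 and from 2.38 to 0.990 for DNA repair without KO replicate 2, and that of a WT summit from 0.683 to 2.27 for regeneration genes without WT replicate 2. In H3K4me2 hepatocyte identity genes went from -75 to 98.2 bp within 10000 bp. A further 19 alternatives for lists with few E2f4 genes had, or were set against, an infinite odds ratio and were left out. In lists of equal length the mean share of WT E2f4 regions found in a KO library was 81.8% rather than 48.7%, because only the strongest peaks are compared. The share of WT H3K4me2 regions found in KO (79.6%) was 84.2% at a −log10 q-value of at least 5, 77.4% in lists of equal length, 80.6% with close regions merged and 76.4% when 50% of the shorter region had to overlap. For H3K27ac (65.8%) these values were 75.7, 71.7, 67.7 and 62.1%. All 8 lay outside a counting interval that is narrow because the regions are many. With single libraries left out, peak numbers in KO were 20.1 to 47.9% of WT, genes with a summit 20.1 to 57.6%, and the share of regions 22.8 to 69.7%. The number of lists retained more often in KO was 1 to 3, the 3 without WT replicate 2. The difference in H3K27ac share between E2f4 genes with and without a KO summit was 1.70 percentage points and 0.791 to 1.67 with single libraries left out, and lost its unadjusted exact-test call without KO replicate 2. It also lost it within 500 bp (1.69) and at a −log10 q-value of at least 5 (1.21), and the cause was not tested. Negative cell cycle regulators passed the enrichment test in 4 settings. Either gene end for all genes, and equal-length lists for the covered lengths of gene lists, were chosen after seeing the data. With the replicate number as a block, KO peak numbers were a geometric mean of 32.2% of WT (16 and 64.6% within numbers). The deviations of libraries with the same number correlated at r = -0.0347 over 216 regions, so no pairing by number was seen region by region. A correlation over regions cannot show a shift common to a whole library, so a batch shared by libraries of the same number stays open. The motif search was not run, and without counts depth limits every statement on a missing peak.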

Other observations

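The test on clustered histone genes was chosen after H3c8 had been seen among the strongest sites, and the screens of gene families were not planned. E2f4 summits were common at the clustered, replication-dependent histone genes, which supply histones to new DNA. Of 57 such genes with H3K4me2, 15 (26.3%) had a summit in both WT libraries, against 5.25% of other genes (odds ratio 6.45, Fisher's exact test, p = 1.87e-07), and 14 of the 15 had one in a KO library. They included H1f2, H2ac7, H2bc7, H3c3, H3c8, H4c1 and H4c14, some of which share a promoter, so that the genes are not independent.

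Families defined by the stem of the gene symbol were screened for E2f4 summits, and 8 of 249 stems with at least 8 genes passed Fisher's exact test after Benjamini-Hochberg adjustment. Some of these families repeat the fixed lists, which hold 9 of the 12 kinesin genes (Kif) with a summit in both WT libraries, all 5 such Mcm genes and 6 of the 7 such Cdc genes. With the genes of all lists left out, 5 of 242 stems passed, and the Kif genes did not, with 3 of 26 (exact test, adjusted p = 1). The 5 were the centrosomal Cep genes with 11 of 37 (exact test, adjusted p = 0.000109), the RNA-binding Lsm genes with 6 of 13 (adjusted p = 0.00135), the nucleoporin genes (Nup) with 7 of 20 (adjusted p = 0.00143), the intraflagellar transport genes (Ift) with 5 of 13 (adjusted p = 0.0109) and the spindle-related Haus genes with 4 of 8 (adjusted p = 0.0123). All 11 Cep genes had a summit in a KO library, as did 4 of the 6 Lsm, 3 of the 7 Nup, 4 of the 5 Ift and 3 of the 4 Haus genes. Some of these summits lie at promoters shared with other genes, so the family cannot be taken as the bound group. Ift80 shares its summit with the list gene Smc4, Ift122 with Mbd4, Ift74 with Plaa and Ift140 with Cramp1l, and Cep89, Lsm3, Nup37 and Haus3 share theirs with Faap24, Xpc, Parpbp and Poln.

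Among the later lists, H3K4me2 of male-biased liver genes differed by -113 bp in KO (percentile 10.3). Second macrophage and neutrophil lists lay at percentiles 72.2 and 6.74 in H3K4me2. In H3K27ac the percentiles were 1.18 for macrophages, 10.3 for neutrophils, 1.46 for the second endothelial list, 72.6 for B cells and 94.8 for T and NK cells.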
